A study of Arabidopsis thaliana with 8 samples.

How the data were processed

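The deposited files hold 1 scanner output per array and a series matrix. Per the file headers, spots were read and background-subtracted by Agilent Feature Extraction 9.5.1.1, and the processed signal is an intensity with no scaling between arrays. Its lowest values are replaced within the array by a surrogate near the error of the background, per the file headers. The deposited mean signal and median background are intensities too, and the flags are 0 or 1. The authors' series matrix holds a ratio on the linear scale: as deposited, each value is the processed signal divided by 1 factor per array, so that each column has a median of 1. Per the labels' protocols, plants were inoculated at 14 days of age with 2 ml of spore suspension, tissue was cut by laser from paraffin sections, mRNA was amplified by global PCR and 250 ng of the amplified cDNA was labelled with Cy3.

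The scanner files were used. After 1417 control spots were left out, 37685 spots with 37478 distinct probes remained. Spots that the software flagged as uneven or as outliers were set to missing on that array. The spot names gave a locus for 26434 spots and none for 11251, which were left out of the gene comparisons. The listed accessions, searched where the names lacked a locus, added none. The names gave 25665 loci, of which 25449 were found in the reference table (assembly TAIR10.1), which served for symbols alone. Repeated spots of a probe were averaged. For the 541 genes with several probes, the probe with the highest mean was taken.

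Signals were put on the log2 scale and each array was shifted by its 75th percentile over the 4725 probes above background on all 8 arrays. The plan written before the data were examined named the 75th percentile of all probes as the main scaling and this one as an alternative; they were exchanged after it was seen that most spots were not above background on 7 of the 8 arrays. The exchange moves the fitted differences of a comparison by 1 constant, and with them the p-values and how many genes lie above or below 0; bounded differences do not all move with it. A gene was tested if its probe was well above background on at least 2 of the 6 arrays of the cortex series and missing on none, which left 14684 genes. The depth of an array is given as its number of spots above background. The number of arrays limits the precision.

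There was 1 array per group, so the groups were compared in a few ways, chosen before the data were examined. An additive limma fit (limma 3.58.1 in R 4.3.3; lmFit and eBayes without trend) with state and time as terms was made over the 6 cortex arrays and gave 3 comparisons: small plasmodia with control cortex, large plasmodia with control cortex, and large with small plasmodia. It has 2 residual degrees of freedom (2.36 prior degrees of freedom, prior SD 1.18), and the median standard error was 1.18. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Another 9 comparisons set 1 array against 1 array and have no test; they count genes at least 4-fold apart whose brighter array was well above background. A gene whose fainter array was not above background entered with a lower bound, taken from the larger of its own signal and the faintest spot well above background on that array. Bounds over both times were made in the same way for a state detected on neither of its arrays. Correlation and shared sign between 14 and 21 dai were described without a p.

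Named genes follow a rule written beforehand. For the tested comparisons, the 10 largest rises and 10 largest falls were taken among genes past the threshold with the same sign at both times and above background, unsaturated, on the 4 arrays compared; as none passed, the same 20 were taken by size from 2806, 3615 and 3535 such genes and are given as values that did not pass. For single arrays, the 10 largest differences each way were taken among genes above background on both. Members of the fixed lists were chosen for mention after their values were seen, and so were the genes named as repeated in all 4 comparisons.

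There were 24 gene lists fixed beforehand: brassinosteroid biosynthesis, brassinosteroid signalling and inactivation, sterol biosynthesis, cytokinin metabolism, cytokinin perception and response, auxin, expansins and xyloglucan endotransglucosylases, cell cycle, salicylic acid, jasmonate and ethylene, tryptophan with indole glucosinolates and camalexin, aliphatic glucosinolates, flavonoids, phenylpropanoids, sugar and starch, abscisic acid and drought, heat shock, photosynthesis, xylem, phloem, endodermis, epidermis, cortex with thalianol, and cytosolic ribosomal proteins. Of 403 members written by symbol and locus, 6 were dropped because the table gave another symbol. A list needed 3 measured members, which the cortex list did not reach: THAS1 was above background only on the array with large plasmodia of 21 dai, and THAH also in infected central cylinder. Lists were tested by camera with a preset correlation of 0.01, and beside it by camera with an estimated correlation and by fry, adjusted over the 23 lists of a comparison. With an estimated correlation camera takes its p from the residual degrees of freedom, 2 in the main fit, so a list could hardly pass whatever its correlation. For ribosomal genes with large plasmodia the estimated correlation was 0.012, near the preset, yet the unadjusted camera p went from 8.91e-06 to 0.0529. For abscisic acid and tryptophan genes it was 0.47 and 0.37, far above the preset, so their preset p may be too small. Fry tests whether the members move one way, not whether they differ from other genes. For single arrays the list median, with bounds entered as values, was placed among 10000 random lists matched on mean signal in 20 bins.

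The scripts were tested on simulated data: with 200 of 14684 genes changed in the comparison of large plasmodia with control cortex, a change of 2 on the log2 scale had the right sign in 91.4% of genes and p below 0.05 in 26.4%, and a change of 4 in 98.0% and 77.3%. With the spread reduced to 0.1 of its size 98.5% of genes changed by 2 passed. Alternatives tried were quantile normalization, the 75th percentile of all probes, normexp background correction with an offset of 50, the authors' values, other filters, the mean of the probes, slide as a term, no time term, an intensity trend, a 2-fold size and leaving out each array. Slide as a term gives the same state estimates as leaving out control cortex of 14 dai, the only array of that time on the second slide. No outlier check was possible with 1 array per group.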

Results

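Gene expression was measured in cells cut by laser from root sections of Arabidopsis ecotype Col-0, either uninfected or infected with Plasmodiophora brassicae, the obligate parasite that causes clubroot. The pathogen grows inside root cells as plasmodia, which are multinucleate bodies without a wall. Central cylinder was taken from control and from infected roots at 14 days after inoculation (dai). Cortex of control roots, host cells with small plasmodia near the central cylinder and enlarged cortex cells with large plasmodia were each taken at 14 and at 21 dai. These make 8 groups with 1 one-colour array each, so there were no replicates and no check of repeatability within a group. The arrays lay on 2 slides. The control cortex array of 14 dai shared a slide with the 21 dai arrays, while the other 14 dai arrays shared the first slide, so infected and control cortex at 14 dai differ in slide as well as in infection.

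The deposited processed signal is an intensity per spot, and 37685 spots were used. Spots well above background numbered 18599 in control central cylinder, 14460 in infected central cylinder, 12896 in control cortex at 14 dai and 11696 in control cortex at 21 dai. With small plasmodia they numbered 10911 at 14 dai and 12520 at 21 dai, and with large plasmodia 15421 and 19721, which is 29.0% to 52.3% of the spots. No spot was saturated. The brightest 1% of spots held 59.0% and 68.5% of all signal on the control cortex arrays of 14 and 21 dai, against 31.2% to 50.4% on the other arrays. Control cortex stood apart on the first principal component, which held 32.0% of the variance. The most similar arrays were infected central cylinder and large plasmodia at 14 dai (Pearson r = 0.75), followed by the arrays with large plasmodia at 14 and 21 dai (r = 0.72). The control cortex arrays of 14 and 21 dai, on 1 slide, correlated at only 0.57, and the arrays with small plasmodia at 0.56. On that slide, control cortex of 14 dai correlated at 0.53 and 0.54 with small and large plasmodia of 21 dai. The number of arrays limits the precision of every value.

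**Figure D1:**
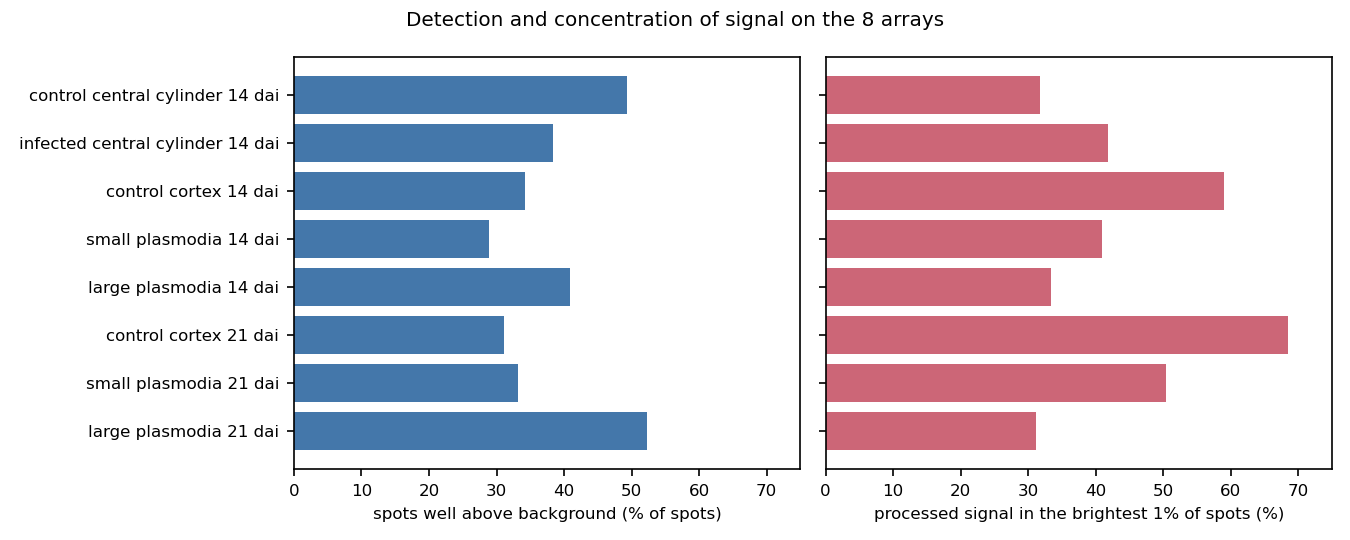
Share of spots well above background and share of the processed signal held by the brightest 1% of spots on each of the 8 arrays (1 array per group).

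The first comparison asked how the infected central cylinder differed from the uninfected one at 14 dai, on the same slide. The largest differences included XTH30 (AT1G32170, xyloglucan endotransglucosylase), 10.10 higher on the log2 scale, ABCG35 (AT1G15210, an ABC transporter), 8.62 higher, and the trypsin inhibitors TI1 (AT2G43510) and TI2 (AT2G43520), 8.37 and 8.06 higher. CCD8 (AT4G32810), a carotenoid dioxygenase of strigolactone synthesis, was at −6.29, the bZIP factor TGA3 (AT1G22070) at −6.50 and the endoglucanase GH9B13 (AT4G02290) at −5.96. Jasmonate genes were higher: of 18 measured members of the jasmonate and ethylene list, 10 were at least 4-fold higher and 1 at least 4-fold lower. The members included LOX3 (AT1G17420) at 5.12, AOC3 (AT3G25780) at 6.46 and JAZ5 (AT1G17380) at 2.63 higher, and OPR3 (AT2G06050) at least 7.82 higher. The list median of 2.32 lay at percentile 99.62 of 10000 random lists matched on signal.

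Both brassinosteroid lists also had medians above that of all genes in the infected cylinder. For synthesis only 1 of 3 genes was above background on both arrays, and signalling genes went both ways (median 1.13). All 3 measured genes of brassinosteroid synthesis were at least 4-fold higher, with CYP90D1 (AT3G13730) 4.94 higher, CPD (AT5G05690) at least 4.05 and ROT3 (AT4G36380) at least 4.44 (percentile 97.74). Of 18 brassinosteroid signalling genes, 7 were at least 4-fold higher and 3 at least 4-fold lower; the receptor BRI1 (AT4G39400) was 3.42 higher and its co-receptor BAK1 (AT4G33430) 6.43 higher, while the transcription factor BES1 (AT1G19350) was at −1.44 (percentile 97.63). Among tryptophan, indole glucosinolate and camalexin genes, 6 of 11 were at least 4-fold higher and 0 lower, among them PAD3 (AT3G26830) at 3.35 and CYP83B1 (AT4G31500) at least 3.93 higher (percentile 98.24). Photosynthesis genes had 3 of 5 members at least 4-fold higher, with LHCA1 (AT3G54890) at 6.47 (percentile 98.39). Lower values stood among expansins and xyloglucan endotransglucosylases, where 7 of 17 members were at least 4-fold lower and 1 higher, such as EXPA4 (AT2G39700) at −4.05 and EXPA5 (AT3G29030) at −4.80 (percentile 1.56). Xylem markers had 4 of 10 members at least 4-fold lower, such as XCP2 (AT1G20850) at −3.12, and 0 higher, with the median within the range of random lists (percentile 10.48).

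In all, 6753 genes were at least 4-fold apart, 4217 higher and 2536 lower in the infected cylinder (62.4% higher), of which 2423 and 1174 were above background on both arrays. The split depended on the scaling: the authors' own scale gave 33.8% higher and normexp with quantile normalization 49.0%. No test can be made on 1 array per group. In such comparisons a value given as "at least" sets the fainter array at the faintest spot that this array could tell from background, or at its own signal if that was higher.

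The next comparison asked what differed between host cells with small plasmodia and control cortex, over both times. The cells with small plasmodia lay near the central cylinder, so root position may differ as well as infection. The values that follow did not pass the test and are fitted log2 differences ± standard error (n = 2 arrays per state). TGG2 (AT5G25980), a myrosinase that cleaves glucosinolates, was at −11.79 ± 0.87 with small plasmodia, and GH9B13 was at −9.19 ± 1.29. The ubiquitin-conjugating enzyme UBC29 (AT2G16740) was at −9.76 ± 2.08, the RNA-binding protein gene GRP8 (AT4G39260) at −8.56 ± 0.88 and the dehydrin ERD14 (AT1G76180) at −8.05 ± 1.08. On the higher side stood a pyruvate decarboxylase gene (AT4G33070, ethanol fermentation) at 8.47 ± 1.23, HMGS (AT4G11820, a step of sterol precursor synthesis) at 7.21 ± 1.24, AOS (AT5G42650, jasmonate synthesis) at 7.09 ± 1.65, the trehalase TRE1 (AT4G24040) at 7.05 ± 1.19 and the desaturase FTM1 (AT1G43800) at 6.94 ± 1.01. The cytokinin oxidase CKX6 (AT3G63440), which breaks down cytokinin, was 6.64 ± 1.16 higher.

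Abscisic acid and drought genes fell as a list relative to the other genes. Of 9 members, 8 had a fitted value below 0, and the list median was −2.34 relative to all genes (camera, adjusted p = 0.00454; adjusted p = 0.883 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 2 did. Examples were RD29A (AT5G52310), at least 859-fold lower, HB12 (AT3G61890), at least 614-fold lower, and HB7 (AT2G46680), at least 60.2-fold lower; RD29B (AT5G52300) was at −2.60 ± 0.92. The difference lay at 14 dai, where the list median was −5.99, against 0.10 at 21 dai. With slide as a term the list stood at −0.16 relative to all genes (adjusted p = 0.891), and leaving out control cortex of 14 dai gave that same value. In uninfected central cylinder 9 of 11 members were also at least 4-fold below control cortex of 14 dai and 0 above it (median −2.77, percentile 23.40), so the 14 dai value may rest on that control array. Between infected and control cylinder, where that array does not enter, 5 of 10 members were at least 4-fold lower and 2 higher (median −1.20, percentile 4.08). The call was also lost without the array with small plasmodia of 14 dai, and among genes above background on all 6 arrays (−2.19, adjusted p = 0.810).

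Cytosolic ribosomal protein genes rose as a list with small plasmodia. Of 221 members 153 had a fitted value above 0, among them AT5G47930 (40S protein S27) at 6.87 ± 1.09, and the median was 1.14 above that of all genes (adjusted p = 0.00454; adjusted p = 0.883 with an estimated correlation). Members that passed numbered 0 over all genes and 0 adjusted over the list alone. The call was lost with slide as a term, at 0.84 above all genes (adjusted p = 0.328), without the array with small plasmodia of 14 dai, at 0.51, and among genes above background on all 6 arrays, at 0.23.

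The jasmonate and ethylene list did not pass with small plasmodia (adjusted p = 0.113), but its 5 members above background on all 6 arrays did (median 3.59 above all genes, adjusted p = 0.0339; adjusted p = 0.937 with an estimated correlation). Of the 20 members tested under the main filter 14 had a fitted value above 0, with 0 past the threshold over all genes and 5 adjusted over the list alone. LOX3 was 3.71 ± 0.88 higher. AOC3 was at least 9.56-fold higher, JAZ1 (AT1G19180) at least 22.5-fold and JAZ8 (AT1G30135) at least 14.3-fold, none of them above background in control cortex. Such bounds set the state that no array detected at the faintest detectable spot of each of its arrays. By time, 10 of 18 members were at least 4-fold higher and 2 lower at 14 dai (percentile 99.71), and 6 of 17 higher and 2 lower at 21 dai (percentile 82.52). Sterol genes had 7 of 12 members at least 4-fold higher and 1 lower at 14 dai (percentile 99.26), and 3 of 13 higher and 2 lower at 21 dai (percentile 71.71). SMT1 (AT5G13710), a sterol methyltransferase, was 3.21 ± 1.49 higher, and DWF5 (AT1G50430), a sterol reductase, at least 26.8-fold higher. The auxin carrier gene AUX1 (AT2G38120) was at least 69.5-fold higher, and the auxin list lay at percentile 98.32 at 21 dai, with 7 of 15 members at least 4-fold higher and 2 lower. The control cortex array of 21 dai is itself low for this list, which may account for part of that value. In the fit over both times 12 of 22 auxin members were above 0 and the list did not pass (camera, adjusted p = 0.706). Heat shock genes had 4 of 7 members above 0, such as HSP90.1 (AT5G52640) at least 21.9-fold higher and ROF2 (AT5G48570) 4.39 ± 0.91 higher, with 0 past the threshold over all genes and 2 adjusted over the list alone (adjusted p = 0.706).

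Tested by limma, 0 of 14684 genes passed an adjusted p of 0.05 with small plasmodia, and the smallest adjusted p was 0.201. Before adjustment 1419 genes had p below 0.05 (860 higher, 559 lower), where 734 are expected by chance; under the 75th percentile of all probes 680 of 1365 were higher. These p-values measure how far the difference repeated at 14 and 21 dai, with 2 residual degrees of freedom. In simulated data for the comparison of large plasmodia with control cortex, 0% of genes changed by 4 on the log2 scale passed, and 29.2% of those changed by 8. At 14 dai 5116 genes were at least 4-fold apart, 3164 higher (61.8%) and 1952 lower, and the 75th percentile of all probes gave 51.2% higher. At 21 dai 4053 genes were at least 4-fold apart, 2231 higher and 1822 lower. Among genes above background on both arrays 1125 were higher and 1070 lower at 14 dai, and 804 higher and 973 lower at 21 dai.

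**Figure D2:**
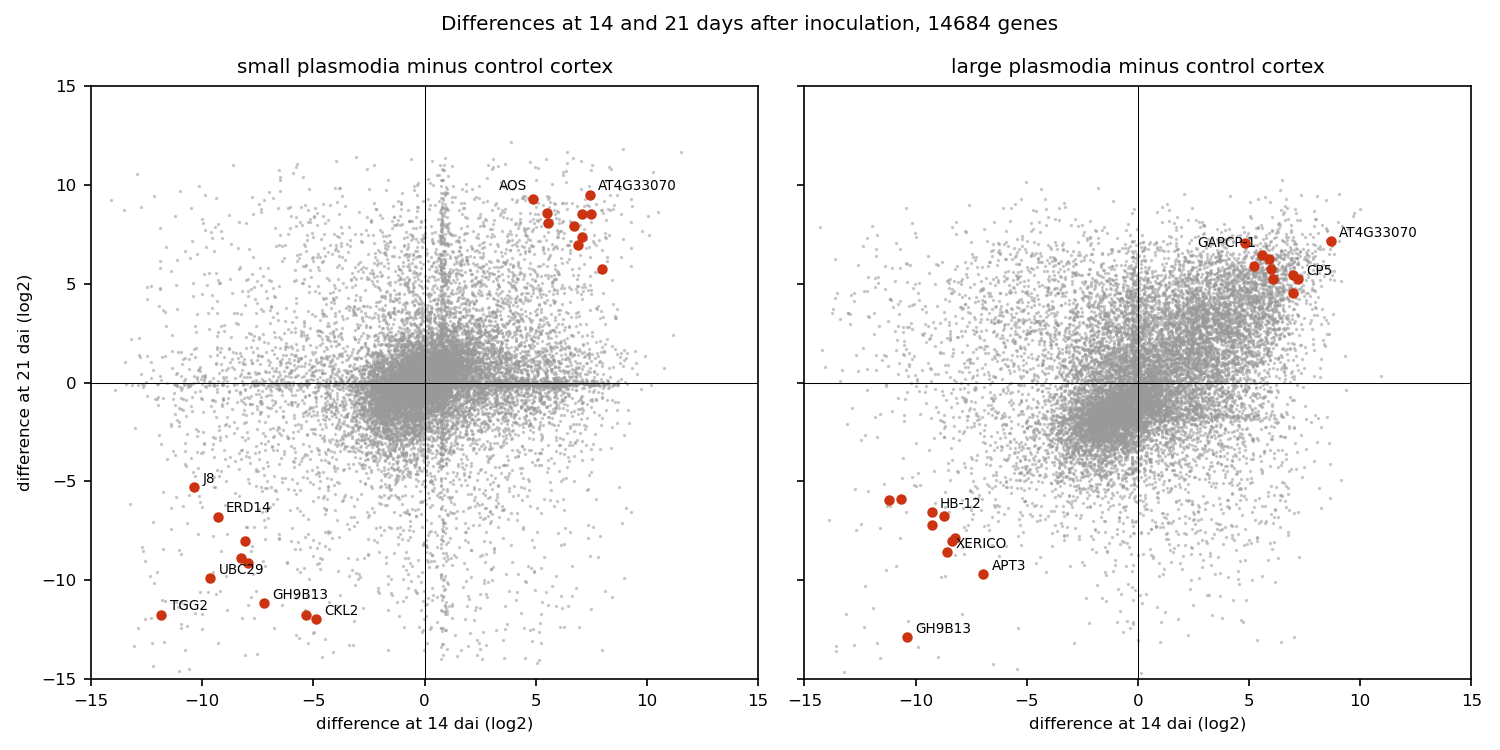
Log2 differences from control cortex at 14 and at 21 dai for the 14684 genes tested, with small and with large plasmodia. Red points are the 20 genes taken by the naming rule in each comparison, some with their symbols; grey points include genes not above background on some of the arrays.

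Enlarged cells with large plasmodia were compared with control cortex in the same way. None of the following values passed the test. GH9B13 was at −11.62 ± 1.29, XERICO (AT2G04240, a RING finger gene of abscisic acid accumulation) at −8.58 ± 1.59, the adenine phosphoribosyltransferase APT3 (AT4G22570) at −8.31 ± 1.09 and the homeobox gene HB12 at −7.92 ± 1.12. The pyruvate decarboxylase gene AT4G33070 was 7.92 ± 1.23 higher and TRE1 6.08 ± 1.19 higher. GAPCP-1 (AT1G79530, a plastid glycolytic dehydrogenase) was 6.01 ± 0.98 higher, the Ran-binding protein gene SIRANBP (AT1G07140) 5.86 ± 1.27 and SHD (AT4G24190), the chaperone of the endoplasmic reticulum, 5.65 ± 1.06. CKX6 was 5.08 ± 1.16 higher.

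Ribosomal protein genes rose as a list with large plasmodia: 165 of 221 members had a fitted value above 0, and the median was 2.12 above that of all genes (adjusted p = 0.000205; adjusted p = 0.803 with an estimated correlation). Members that passed numbered 0 over all genes and 0 adjusted over the list alone; AT3G04920 (40S protein S24) was 5.56 ± 0.89 higher. The call held with slide as a term (adjusted p = 0.0188; adjusted p = 0.865 with an estimated correlation). The same list was also higher in control central cylinder than in control cortex, by 1.75 relative to all genes.

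Abscisic acid and drought genes fell as a list with large plasmodia as well. All 9 members had fitted values below 0, and the median was −3.29 relative to all genes (adjusted p = 0.00715; adjusted p = 0.803 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 2 did. HB12 was at −7.92 ± 1.12, HB7 at −4.07 ± 2.28 and RD29B at −3.20 ± 0.92. The list median was −6.52 at 14 dai, against the control cortex array that uninfected cylinder also lay below, and −0.54 at 21 dai. The call was lost with slide as a term or without control cortex of 14 dai (−0.71 relative to all genes, adjusted p = 0.467) and under quantile normalization (−1.87). It was lost as well among genes above background on all 6 arrays (−2.57, adjusted p = 0.375).

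Auxin genes stood out at 21 dai, within a slide, where 16 of 27 measured members were at least 4-fold higher with large plasmodia and 1 lower (median 2.61, percentile 99.91). The control cortex array of 21 dai is itself low for this list, at percentile 0.96 against that of 14 dai, and may account for part of the value. Over both times 14 of 22 members had a fitted value above 0, with 0 past the threshold over all genes and 0 adjusted over the list alone. The list median of 2.37 above all genes did not pass (adjusted p = 0.111). It passed with slide as a term (adjusted p = 0.0198; adjusted p = 0.865 with an estimated correlation) and without the array with large plasmodia of 14 dai (adjusted p = 0.0325; 0.901 with an estimated correlation). GH3.5 (AT4G27260), an auxin-conjugating enzyme, was at least 11.3-fold higher and the nitrilase gene NIT2 (AT3G44300) at least 14.9-fold. Sterol genes had 13 of 16 members above 0 and a median 1.86 above all genes (adjusted p = 0.0967), with SMT1 3.68 ± 1.49 and SMT2 (AT1G20330) 4.38 ± 1.47 higher, and SMO2-1 (AT1G07420) at −6.62 ± 1.45. At 14 dai 10 of 15 sterol genes were at least 4-fold higher and 1 lower (percentile 99.93). The sterol list passed when either array with small plasmodia or that with large plasmodia of 21 dai was left out, but with an estimated correlation the adjusted p was 0.910, 0.913 and 0.956 without small plasmodia of 14 dai, small of 21 dai and large of 21 dai. The jasmonate list had 14 of 20 members above 0 (adjusted p = 0.289) and did not pass. Its 5 members above background on all 6 arrays did (median 3.61 above all genes, adjusted p = 0.00160; adjusted p = 0.476 with an estimated correlation). Of all 20 members 0 passed over all genes and 0 adjusted over the list alone; AOS was 4.67 ± 1.65, JAZ5 4.26 ± 1.52 and LOX3 2.98 ± 0.88 higher, and LOX4 (AT1G72520) was at −3.95 ± 1.15.

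Other lists went apart. Sugar and starch genes had 15 of 24 members above 0, with 4 adjusted over the list alone and 0 over all genes (adjusted p = 0.490). SUS1 (AT5G20830), a sucrose synthase, was 3.24 ± 1.15 higher, the starch phosphorylase PHS2 (AT3G46970) at least 46.4-fold higher and the cytosolic invertase CINV1 (AT1G35580) at −4.44 ± 0.97. At 21 dai 13 of 26 of these genes were at least 4-fold higher and 3 lower (percentile 99.02). Expansins and xyloglucan endotransglucosylases had 7 of 17 members at least 4-fold lower and 3 higher at 14 dai (percentile 0.03), but 8 of 23 higher and 4 lower at 21 dai (percentile 75.75). EXPA1 (AT1G69530) was at least 66.9-fold higher over both times, and XTH9 (AT4G03210) at −3.81 ± 1.31. Salicylic acid genes had 6 of 7 members below 0 (adjusted p = 0.456), among them WRKY70 (AT3G56400) at −3.25 ± 1.07, while EDS5 (AT4G39030) was at least 112-fold higher. Phloem markers had 2 of 5 members above 0, with 0 past the threshold over all genes and 1 adjusted over the list alone (adjusted p = 0.861). Cytokinin response genes had 8 of 10 members below 0 (adjusted p = 0.423), and cytokinin metabolism genes 5 of 11 above 0 (adjusted p = 0.810). Epidermis and root hair markers had 4 of 7 members at least 4-fold lower at 21 dai and 1 higher (percentile 0.39). Cell cycle genes had 9 of 17 members above 0 (adjusted p = 0.810), with the cyclin CYCD3;1 (AT4G34160) at least 16.0-fold higher and CYCB1;2 (AT5G06150) at least 123-fold lower. Phenylpropanoid genes had 8 of 11 members above 0 (adjusted p = 0.496), aliphatic glucosinolate genes 2 of 6 (adjusted p = 0.456), flavonoid genes 1 of 5 (adjusted p = 0.490) and endodermis markers 4 of 7 (adjusted p = 0.701).

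By limma 0 genes passed with large plasmodia, the smallest adjusted p being 0.173, and 2907 had an unadjusted p below 0.05 (2030 higher, 877 lower). That split depended on the scaling: under the 75th percentile of all probes 1160 of 3206 were higher, and under normexp 1079 of 2286. At 14 dai 6475 genes were at least 4-fold apart, 4229 higher (65.3%) and 2246 lower. The share higher was 40.2% under the 75th percentile of all probes, 51.2% under quantile normalization and 55.2% under normexp. At 21 dai 7894 genes were apart, 4373 higher (55.4%) and 3521 lower, and that share was 34.8% under the 75th percentile of all probes and 41.5% under quantile normalization. Among genes above background on both arrays the split turned, with 1357 higher and 1562 lower at 14 dai and 1214 higher and 2429 lower at 21 dai. CHLI1 (AT4G18480), a subunit of magnesium chelatase, was at −12.86 at 21 dai, and LOX1 (AT1G55020), a lipoxygenase, 7.35 higher.

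**Figure D3:**
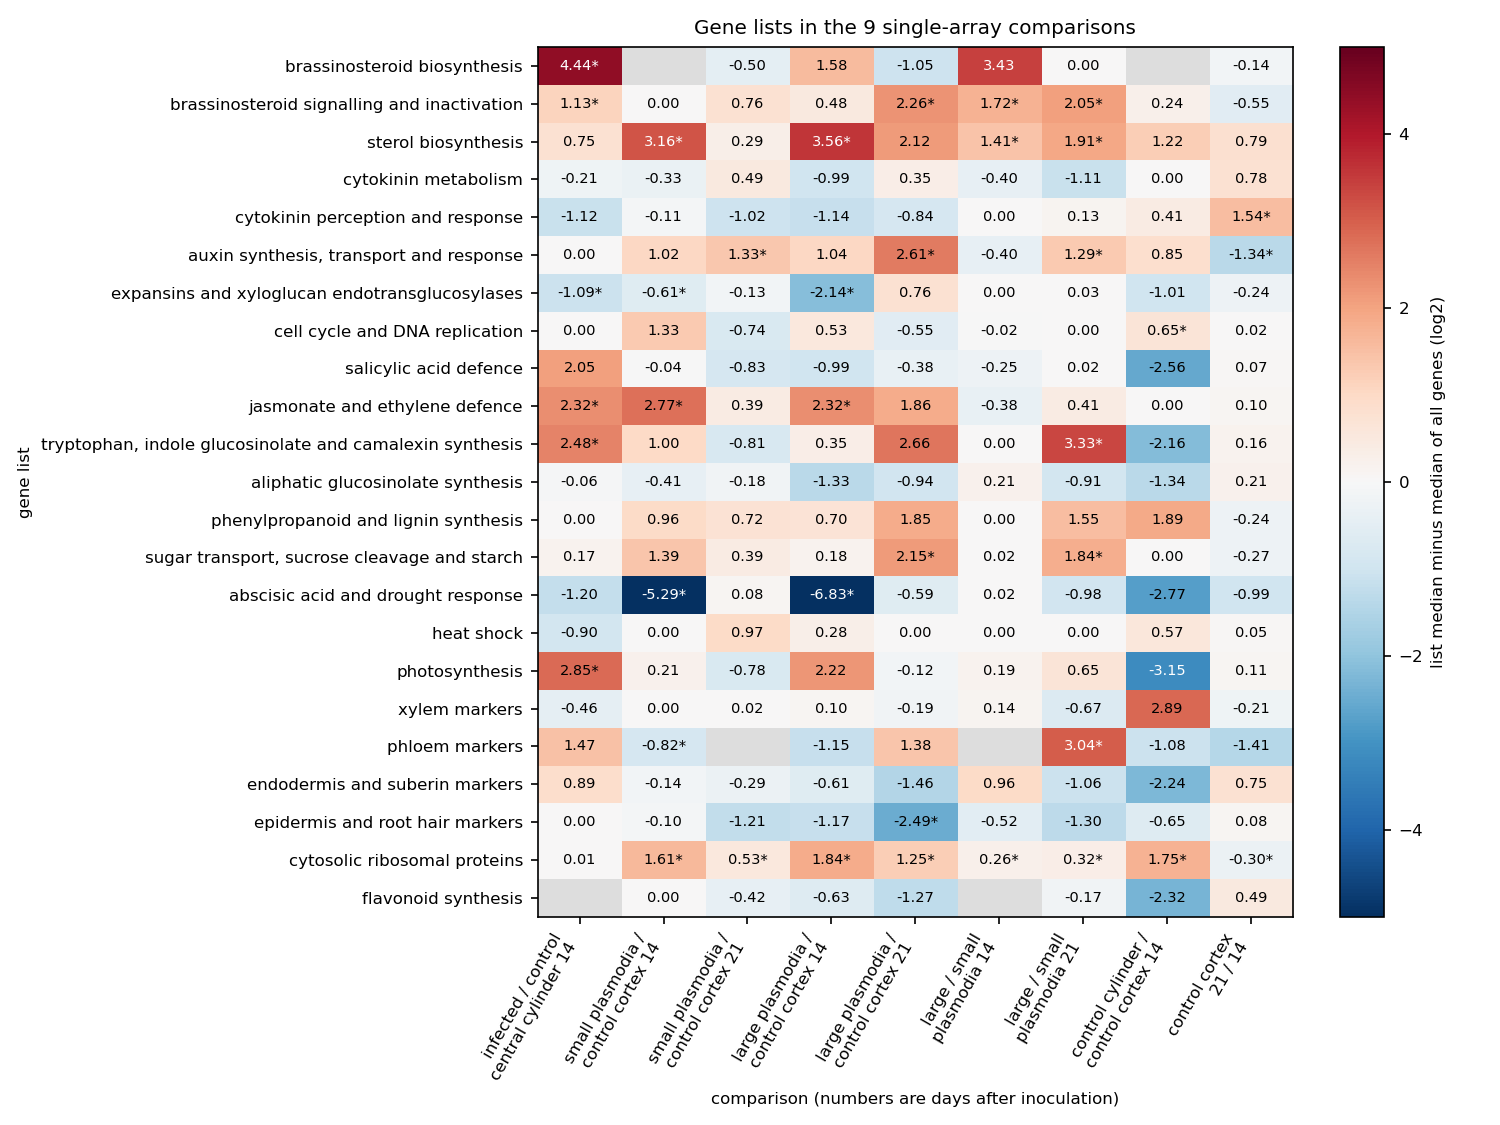
Median log2 difference of each gene list minus that of all genes in the 9 comparisons of single arrays. An asterisk marks medians in the outer 2.5% of matched random lists on either side, and grey fields had fewer than 3 measured members.

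Large and small plasmodia were compared to ask which host genes differed between them, within a slide at each time. Small plasmodia lay near the central cylinder and large ones in the cortex area, so plasmodium size and root position cannot be told apart. The labels name no stages, and "between the stages" below stands for this comparison. The following fitted values did not pass the test. AAE5 (AT5G16370, an acyl-activating enzyme) was at −5.47 ± 1.07 with large plasmodia, WRKY22 (AT4G01250, a defence transcription factor) at −5.02 ± 1.96 and the pectate lyase gene AT4G24780 at −5.07 ± 1.38. The sorting nexin SNX1 (AT5G06140) was 4.62 ± 0.88 higher, the cation exchanger CHX18 (AT5G41610) 4.39 ± 1.11 and SHD 4.39 ± 1.06.

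Tryptophan, indole glucosinolate and camalexin genes rose as a list with large plasmodia. Of 14 members 12 had a fitted value above 0, and the median was 1.93 above that of all genes (adjusted p = 0.0368; adjusted p = 0.877 with an estimated correlation). Members that passed numbered 0 over all genes and 0 adjusted over the list alone. ASA1 (AT5G05730), the first enzyme of tryptophan synthesis, was 3.49 ± 0.95 higher. The cytochrome P450 genes CYP79B2 (AT4G39950), CYP83B1 and CYP71A12 (AT2G30750) were at least 16.4-fold, 8.58-fold and 6.19-fold higher. The list median was 0.83 at 14 dai and 3.74 at 21 dai. Between single arrays 2 of 15 members were at least 4-fold higher and 2 lower at 14 dai (percentile 46.30), while at 21 dai 9 of 16 members were at least 4-fold higher and 0 lower (percentile 99.95). The call was lost under quantile normalization (2.08 above all genes, adjusted p = 0.0573), under normexp (0.89) and among genes above background on all 6 arrays (1.76, adjusted p = 0.0535). It was lost too without either plasmodium array of 21 dai, at 1.06 without small plasmodia, and the value was 3.39 without that with large plasmodia of 14 dai.

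Phloem markers had all 5 tested members above 0 with large plasmodia (median 2.72 above all genes, adjusted p = 0.236), with 0 past the threshold over all genes and 1 adjusted over the list alone. At 21 dai 5 of 8 were at least 4-fold higher and 0 lower (percentile 99.99), including PP2-A1 (AT4G19840) at least 5.62 higher, APL (AT1G79430) at least 4.21 and OPS (AT3G09070) at least 4.08. Ribosomal protein genes did not pass between the stages (adjusted p = 0.237), but did among genes above background on all 6 arrays (median 0.73 above all genes, adjusted p = 0.00271; adjusted p = 0.729 with an estimated correlation). Sterol genes had 11 of 16 members above 0 (adjusted p = 0.103) and lay at percentile 98.31 at 14 dai and 98.80 at 21 dai. EXPA15 (AT2G03090) was 3.81 ± 1.84 higher. AUX1 was at −3.63 ± 1.00, although 10 of 27 auxin genes were at least 4-fold higher at 21 dai and 3 lower (percentile 98.67). At 14 dai the tested auxin genes had no such rise, with a median of −0.40 against −0.23 for all genes.

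By limma 0 genes passed between the stages, with a smallest adjusted p of 0.419, and 1284 had an unadjusted p below 0.05 (1089 higher, 195 lower), and under the 75th percentile of all probes 707 of 1184 were higher. At 14 dai 3903 genes were at least 4-fold apart, 2261 higher (57.9%) and 1642 lower, with 43.8% higher under the 75th percentile of all probes. FATB (AT1G08510), a thioesterase of fatty acid synthesis, was 5.74 higher and the light signalling repressor gene COP1 (AT2G32950) at −6.46. At 21 dai 6576 genes were apart, 3780 higher (57.5%) and 2796 lower. That share was 32.5% under the 75th percentile of all probes and 41.9% under quantile normalization. Among genes above background on both arrays the split turned at both times, with 717 higher and 861 lower at 14 dai and 1092 higher and 2136 lower at 21 dai. PCK1 (AT4G37870), a gluconeogenic carboxykinase, was 6.61 higher at 21 dai and the replication protein gene RPA1A (AT2G06510) at −9.33.

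Brassinosteroids, which the series title names, were followed through all cortex samples with fixed lists for synthesis and for signalling. With small plasmodia 10 of 19 signalling genes had a fitted value above 0 and the median was −0.17 relative to all genes (adjusted p = 0.983). With large plasmodia 11 of 19 were above 0, and the median was 1.43 above all genes (adjusted p = 0.423), with 0 past the threshold over all genes and 6 adjusted over the list alone. The kinase BIN2 (AT4G18710) was at least 20.8-fold higher with small and 13.8-fold higher with large plasmodia. The phosphatase gene BSL3 (AT2G27210) was 3.22 ± 0.98 higher with large plasmodia, and the transcription factors BEH2 (AT4G36780) and BEH3 (AT4G18890) were at least 44.5-fold and 17.0-fold higher. BRI1 differed by 0.32 ± 3.47, since its control value at 21 dai was 9.55 above that at 14 dai, and BAK1 by −0.09 ± 0.90. At 21 dai 11 of 21 signalling genes were at least 4-fold higher with large plasmodia than in control cortex and 3 lower (percentile 97.99), and at 14 dai 9 of 19 were higher and 2 lower (percentile 64.28). Between the stages, 6 of 16 were higher and 0 lower with large plasmodia at 14 dai (percentile 99.00), and 10 of 19 higher and 3 lower at 21 dai (percentile 98.81), but the list did not pass over both times (median 1.41 above all genes, adjusted p = 0.305). Only 4 synthesis genes could be tested, with medians of −0.40, 0.59 and 1.30 relative to all genes with small plasmodia, with large plasmodia and between them (adjusted p = 0.799, 0.944 and 0.785). ROT3, a hydroxylase of brassinosteroid synthesis, was at least 4.55-fold higher with large plasmodia, and CYP90D1 was at −1.19 ± 0.92. Leaving out 1 array moved the signalling median with large plasmodia between 0.03, without control cortex of 21 dai, and 2.46, without control cortex of 14 dai.

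**Figure D4:**
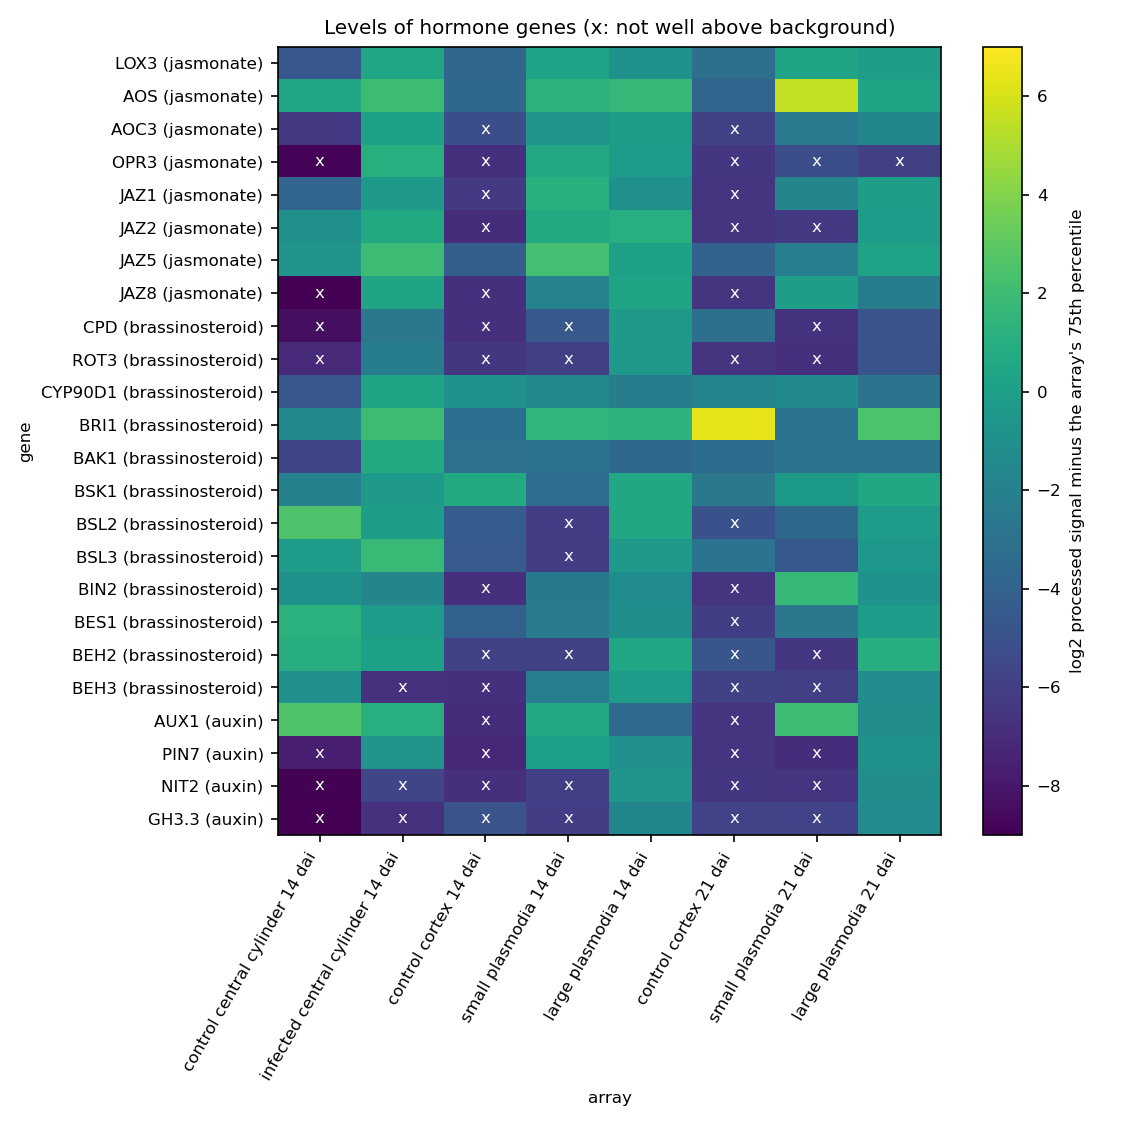
Level of jasmonate, brassinosteroid and auxin genes on each of the 8 arrays, as log2 processed signal minus the array's 75th percentile over probes above background on all arrays. A cross marks a gene not well above background on that array.

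Agreement between the times was asked of genes, with no p since genes are not replicates. Differences at 14 and 21 dai correlated at r = 0.147 with small plasmodia against control cortex, 0.285 with large plasmodia and 0.152 between the stages, and 58.5%, 65.3% and 60.5% of genes had the same sign. With large plasmodia 383 genes measured on all 4 arrays were at least 4-fold higher at both times, where independence gives 163, and 515 lower, where it gives 306. With small plasmodia 179 were higher, where 88.6 are expected, and 227 lower, where 100 are. Between the stages 140 were higher with large plasmodia at both times, where 70.9 are expected, and 102 lower, where 111 are. Genes at least 4-fold apart in opposite directions at 14 and 21 dai numbered 206 with small plasmodia, 331 with large and 213 between the stages. A count above independence does not alone show that the differences repeated. AT4G33070, CP5 (AT1G64720), TRE1, FTM1, AOS and CKX6 were at least 4-fold higher in all 4 comparisons of plasmodium samples with control cortex, and GH9B13, UBC29, CKL2 (AT1G72710), ERD14 and XERICO lower in all 4. These comparisons share the control cortex arrays. Uninfected central cylinder was also at least 4-fold below control cortex of 14 dai for 164 of the 185 genes lower in all 4 (GH9B13 at −5.07, UBC29 at −9.70, ERD14 at −4.11) and at least 4-fold above it for 59 of the 84 genes higher in all 4, against 44.8% and 14.7% of all genes measured on the 6 cortex arrays. Small and large plasmodia share their control array at each time: their differences correlated at 0.750 at 14 dai and 0.638 at 21 dai, where unchanged genes gave 0.501 at 14 dai in simulated data. The simulation gave control and plasmodium arrays the same spread. Over the common probes the log2 SD was 2.90 and 2.88 in control cortex of 14 and 21 dai, against 1.87 to 2.29 with plasmodia. The excess over the simulated value therefore does not show a shared response.

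Control central cylinder was set against control cortex at 14 dai to see how the tissues differ without infection, on different slides. The amino acid permease AAP6 (AT5G49630) was 8.42 higher in the central cylinder, the glucosinolate transporter GTR2 (AT5G62680) 7.68 higher and the auxin response gene IAA13 (AT2G33310) 7.68 higher. TGG2 was at −12.62, the calcium sensor CBL1 (AT4G17615) at −12.37 and the receptor-like gene CRN (AT5G13290) at −12.75. Xylem markers had 6 of 11 members at least 4-fold higher and 2 lower (percentile 97.31), with XCP2 4.09 higher, HB8 (AT4G32880) 4.15 higher and ACL5 (AT5G19530) at least 7.37 higher. Phloem markers had 1 of 6 higher and 2 lower, among them APL at −6.66 or below. Cell cycle genes lay at percentile 97.98, with 8 of 23 higher and 5 lower. All 5 photosynthesis genes and 4 of 6 endodermis markers were at least 4-fold lower. In all, 9578 genes were at least 4-fold apart, 4284 higher (44.7%) and 5294 lower. The share higher was 34.0% under the 75th percentile of all probes, 57.7% under normexp and 68.6% on the authors' scale.

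Control cortex at 21 dai was compared with control cortex at 14 dai, within a slide, to see how uninfected cortex differed between the times. With 1 array per time, age cannot be told apart from the cutting and amplification of each sample. Of 10 drought and abscisic acid genes 4 were at least 4-fold lower at 21 dai and 0 higher, with the list median within the range of random lists (percentile 10.92); HB7 was at −6.43, COR15A (AT2G42540) at −8.37 and ABI1 (AT4G26080) at −9.95 or below. Cytokinin response genes lay at percentile 99.30, where ARR5 (AT3G48100) and ARR7 (AT1G19050) were at least 3.12 and 4.84 higher but ARR9 (AT3G57040) was at −8.77. Auxin genes lay at percentile 0.96, with 5 of 11 at least 4-fold lower, such as PIN3 (AT1G70940) at −5.62, and 1 higher. The cyclin CYCB1;2 was at −11.11, the ubiquitin extension gene UBQ5 (AT3G62250) at −11.74, and the splicing factor gene SCL30 (AT3G55460) 12.06 higher. In total 3373 genes were at least 4-fold apart, 1545 higher and 1828 lower, but 801 higher and 763 lower among genes above background on both arrays.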

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

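The tests weighed below were chosen after the result was seen. The following values stand apart for a difference between times, which was not tested. Genes of brassinosteroid synthesis had a median 1.58 above all genes with large plasmodia against control cortex at 14 dai and −1.05 at 21 dai. Phloem markers had a median of −1.15 relative to all genes in that comparison at 14 dai and 1.38 at 21 dai. Among 11200 spots without a locus, which entered no gene comparison, 142 (1.27%) were above background on all 4 plasmodium arrays and on neither control cortex array, against 112 (1%) the other way round. Spots with a locus did so more often (2.27%, against 1.03% the other way round), so the count does not set unnamed spots apart. Of the 142 spots 95 were also above background in control central cylinder.

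Many genes were far below control cortex at 14 dai in both plasmodium samples: 1691 were at least 4-fold lower in both. At 21 dai, where infected and control samples share a slide, those of them with a value had a median of −0.43 with small plasmodia (1296 genes) and 0.36 with large plasmodia (1567 genes), so a difference between the slides could account for the set as a whole. It is not the whole cause for every gene, since of 4279 genes measured on the 6 cortex arrays 185 were lower with both plasmodium samples at both times, where independence gives 74.0, a ratio of 2.50, which does not decide whether chance bright spots on single control arrays made the rest. Uninfected central cylinder was at least 4-fold below control cortex for 164 of the 185 genes as well (median −3.98), GH9B13, UBC29 and ERD14 among them, so a property of the control cortex tissue or of its arrays could account for most of them without infection. That value uses the control cortex array by which the genes were chosen, and a change in host cells stays open too. GH9B13 was also among the largest falls in infected against control central cylinder, where control cortex does not enter.

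The jasmonate and ethylene list was higher with plasmodia at 14 dai, where slide and infection go together; in the central cylinder, within a slide, its median was 2.32, which argues against the slides as the cause in infected roots at large. It does not exclude a part of the slides in the cortex values: within a slide at 21 dai the list stood 0.39 above all genes with small plasmodia (percentile 82.52) and 1.86 with large (percentile 97.17), and with slide as a term it stood at 1.13 and 1.38 (adjusted p = 0.608 and 0.554). In the cylinder its percentile of 99.62 argues against fewer detected probes on the control array as the cause there. The control cylinder had more spots above background than the infected one. The cylinder cannot settle this for the cortex. Control cortex of 14 dai had more such spots than small plasmodia of 14 dai (12896 against 10911). In the other comparisons of plasmodia with control cortex it had fewer, and detection as a cause was not tested there. What remains is a hypothesis that infected roots carry more jasmonate transcripts, which rests on the cylinder more than on the cortex and was formed on the same arrays. Over both times the list did not pass under the filter chosen beforehand. Its 5 members above background on all 6 arrays did, but not with an estimated correlation (adjusted p = 0.937 with small and 0.476 with large plasmodia), where a list could hardly pass.

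Cytosolic ribosomal protein genes were higher with plasmodia than in control cortex. Transcripts of the pathogen on plant probes are not needed for such a difference, since uninfected central cylinder was also 1.75 above all genes against control cortex. That comparison is between uninfected tissues on different slides, so it cannot exclude such transcripts as a cause in the plasmodium samples. A property of the control cortex arrays could account for much of the pattern: the list was 1.61 and 1.84 above all genes with small and large plasmodia at 14 dai and 0.53 and 1.25 at 21 dai, but 0.0088 between infected and control cylinder (though at percentile 95.37 of matched random lists). It need not be the whole cause, since between large and small plasmodia, where control cortex does not enter, the list was still 0.26 and 0.32 above all genes at 14 and 21 dai (percentile 100 at both), and what made that difference stays open. Whether that property lies in the tissue or in the sample preparation was not tested.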

How the results depend on the processing

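Settings for the lists past the threshold other than the estimated correlation and fry, the fit without control cortex, and estimated correlations within an alternative were chosen after the results were seen. The count of 0 genes past the threshold held in all 49 pairs of a comparison and an alternative. Of the list medians 128 kept direction and call, 8 reversed, 13 lost the call and 4 moved. Most of these belong to the brassinosteroid lists, which had no call to lose, so the lost calls all fall on the fewer medians of lists with a call. Few spots above background (29.0% to 52.3%) limit all counts. The cause was not tested for any change below, apart from filters and sizes, which change which genes count.

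With slide as a term the brassinosteroid signalling median with small plasmodia reversed from −0.17 to 0.39 and the synthesis median with large plasmodia from 0.59 to −1.17. From 21 dai alone, abscisic acid genes with small plasmodia stood at 0.0712, reversed, and with large plasmodia at −0.69; ribosomal genes stood at 0.42 and 1.78, and tryptophan genes between the stages at 4.15. Calls were lost with slide as a term for abscisic acid genes with small (−0.16) and large plasmodia (−0.71) and for ribosomal genes with small plasmodia (0.84), under quantile normalization for abscisic acid genes with large plasmodia (−1.87) and tryptophan genes (2.08), and for these under normexp (0.89). Among genes above background on all 6 arrays every call but that of ribosomal genes with large plasmodia was lost (adjusted p = 0.810 and 0.375 for abscisic acid genes with small and large plasmodia, 0.810 for ribosomal genes with small plasmodia, 0.0535 for tryptophan genes), and the remaining ribosomal call was lost there with an estimated correlation (adjusted p = 0.476). Without a filter the sterol, jasmonate and tryptophan lists with large plasmodia, and the sterol and ribosomal lists between the stages, passed as well, but not with an estimated correlation (adjusted p = 0.546, 0.546 and 0.652 with large plasmodia and 0.686 between the stages). All 5 calls were lost with an estimated correlation (adjusted p = 0.883, 0.803 and 0.877) and with fry (adjusted p = 0.679 and 0.239 for abscisic acid genes with small and large plasmodia, 0.236 and 0.0966 for ribosomal genes, 0.671 for tryptophan genes). Losses with an estimated correlation cannot weigh the calls, since that p rests on so few residual degrees of freedom that a list could hardly pass. The correlation itself was estimated at 0.47 for abscisic acid genes and 0.37 for tryptophan genes, against the preset of 0.01. For these lists the preset p may thus be too small, while for ribosomal genes the estimate was 0.012.

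Leaving out 1 array at a time moved abscisic acid genes between −6.18 and −0.16 with small and between −7.96 and −0.71 with large plasmodia, ribosomal genes between 0.51 and 1.43 and between 1.73 and 2.36, and tryptophan genes between 1.06 and 3.39. Brassinosteroid synthesis moved between −0.97 and 0.31 with small plasmodia, −1.17 and 1.99 with large, and 0.05 and 2.73 between them; signalling between −1.34 and 0.39, 0.03 and 2.46, and 0.01 and 1.88. A lone array of a state was assumed to vary like the others.

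Counts of 4-fold differences under normexp were 1732 (infected cylinder), 2462 (cylinder against cortex), 2535 and 2444 (small and large plasmodia at 14 dai), 2335 and 2519 (at 21 dai), 1727 and 1863 (between the stages) and 2040 (control cortex by time). With both arrays above background they were 3597, 5031, 2195, 2919, 1777, 3643, 1578, 3228 and 1564 in that order. Without a filter the cylinder counts were 14281 and 16620, and 6301 between the stages at 14 dai. At 2-fold they were 9986 with large plasmodia at 14 dai, 6912 with small at 21 dai, 7437 and 11297 between the stages and 5347 in control cortex by time. Shared signs moved to 62.7% (small plasmodia) and 64.8% (between the stages) for genes above background on all 6 arrays, to 68.8% (large plasmodia) and 61.8% (between the stages) under quantile normalization, and to 67.7% (large plasmodia) under normexp.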

Other observations

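The test of this part was written down before its result was seen, after AT4G33070, FTM1 (AT1G43800) and AT1G19530 had been seen among the largest differences with small plasmodia. Genes that plants raise when oxygen is short were high in infected samples. ADH1 (AT1G77120), alcohol dehydrogenase, was at least 8.39 higher with small plasmodia than in control cortex at 14 dai and at least 8.73 at 21 dai, and with large plasmodia at least 7.56 and 5.85. PCO2 (AT5G39890), a cysteine oxidase that senses oxygen, was 5.39 and 6.54 higher with small and 4.40 and 3.79 with large plasmodia. ACR7 (AT4G22780) was 4.15 and 7.08 higher with small plasmodia and 4.39 and 5.43 with large, and the transcription factor HRA1 (AT3G10040) 1.42 and 6.28 with small and 3.75 and 2.17 with large. Some members went the other way, at 14 dai among them PCO1 (AT5G15120) at −6.53 and −5.24 and ASP2 (AT5G19550) at −2.61 and −3.26, and at 21 dai UKL3 (AT1G55810) at −3.51 and −4.92 or below. At 21 dai PCO1 was at least 8.82 and 7.34 higher with small and large plasmodia and ASP2 at least 9.75 and 7.83. Control cortex of 14 dai was itself high for both, at 5.60 and 6.12, and that of 21 dai not above background, so the swing follows single control arrays and part of the 21 dai medians may rest on them.

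The hypothesis was a wider response to low oxygen, tested on 22 such genes written down without those 3. Their median against control cortex was 2.16 with small and 1.61 with large plasmodia at 14 dai, and 4.49 and 2.83 at 21 dai. It lay at percentiles 99.79, 98.71, 100 and 99.88 of 10000 matched random lists, as the hypothesis requires. Members at least 4-fold higher and lower were 9 and 3 of 17 with small and 10 and 3 of 21 with large plasmodia at 14 dai, and 12 and 1 of 16 and 12 and 1 of 19 at 21 dai. In infected against control central cylinder, 16 of the 22 genes were at least 4-fold higher and 1 lower, with a median of 3.28. Uninfected central cylinder did not share this pattern as a list: against control cortex 7 of 20 members were at least 4-fold higher and 7 lower (percentile 68.02), a comparison added after the result was seen. It uses the control cortex array of 14 dai, which was high for PCO1 and ASP2, both among the lower members (−11.3 and −3.89). It therefore cannot exclude a difference between the tissues. Single genes named above were higher in uninfected central cylinder too, ADH1 by at least 5.18, AT4G33070 by 4.14, AT1G19530 by 3.56 and ACR7 by 2.04, so their values do not set infected cells apart from every uninfected tissue. PCO2 was at −3.30 and HRA1 at −1.93. In these infected samples the median stood above that of all genes under all 5 scalings, the lowest being 1.08. These values are consistent with low oxygen in infected tissue, or with handling of infected roots that differed from that of controls, which the arrays do not separate.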
